A study of Homo sapiens with 4 samples.

How the data were processed

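RNA of the untethered line B49.5 and the tethered line B49.5 74t3 was compared on 4 two-colour spotted arrays, a balanced dye swap. Per the labels' protocols, cells were grown in serum-containing medium and harvested before confluence, total RNA was extracted with Trizol and treated with DNase, and cDNA was labelled directly with Cy3 or Cy5; the molecule field of the labels reads polyA RNA instead. Per the labels, the arrays are 4 biological replicates. The limma p-values of single features rest on the spread between these, as far as the residual described below holds it. Fisher's tests, binomial intervals and camera with the preset correlation take genes as units and do not measure that spread.

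Per the file headers, each array was quantified with BlueFuse for Microarrays 3.2 from scans at 532 and 635 nm, in 48 blocks of spots, 30000 spots in all. The deposited spot amplitudes are intensities on a linear scale, 1 per channel, with background handled inside the program and no separate background column. The deposited log2 ratios are log2 of the Cy5 over the Cy3 amplitude, neither centred nor turned for the swap. The program's probability that a spot is on and its confidence in the spot are deposited as fractions between 0 and 1, per the file headers with classes A to E, E being confidence under 0.1. Positions are those of the files, on NCBI build 35. The value table of the series holds the same log2 ratios: 30000 of 30000 values on each array equalled the scanner program's Cy5 over Cy3 ratio, with medians of −0.249, −0.123, −0.070 and 0.473 on replicates 1 to 4; their scale, centring and direction are thereby known.

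The direction was taken from the sample titles and the file headers, which place the tethered line in Cy5 on replicates 1 and 3 and in Cy3 on replicates 2 and 4. The dye fields of the labels give the opposite dye for each line on every array; this would turn the sign of every value and exchange the higher and lower counts with their p-values, and would leave the total of calls as it is. No value in the files was used to set it.

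Amplitudes were used as deposited, since background was already handled; normexp correction with an offset of 50, planned as the main setting, and with an offset of 16 were run as alternatives. Log2 Cy5 over Cy3 ratios were normalised within each array by global loess (span 0.3) in limma 3.58.1 under R 4.3.3. The 410 control spots, 312 of them GAPDH and 98 blank or empty, had weight 0 and were left out. Spots of class E also had weight 0, which removed 39.0%, 51.7%, 46.8% and 54.9% of spots on replicates 1 to 4. A probe was kept if a channel was on (probability of at least 0.5) on at least 2 arrays and if it had a usable spot on at least 3 arrays and in both dye orientations. The exclusion of class E and the minimum of 3 arrays were chosen after the raw values and the spots of TMPO had been seen and before any model was fitted. Spots of 1 probe were averaged, and for a gene with several probes the probe of highest mean intensity was used.

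Of 28830 probes, 13538 were named by matching their accession to a RefSeq gene table of assembly GRCh38.p14, used for names only, and 806 by a symbol in the file's own description; 14486 had no name here and were tested as unnamed features. Chromosome Y was left out of the chromosome tests.

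A linear model with a probe-specific dye effect and a tethered term of 1 or −1 by orientation was fitted with lmFit and eBayes (prior degrees of freedom 5.13), with Benjamini-Hochberg adjustment at 0.05, two-sided. With the dye effect fitted, the residual compares replicate 1 with 3 and replicate 2 with 4 only; where replicate 2 is missing for a gene, replicate 4 is fitted exactly and its error does not enter the SE, and likewise for replicate 2 where replicate 4 is missing. Gene lists, chromosomes and windows of chromosome 4 with at least 5 measured members were tested with camera on the moderated statistics (correlation 0.01), and with an estimated correlation and fry on features measured on all 4 arrays. Per-array list medians have 95% bootstrap intervals over members (2000 resamples). Shares on chromosome 4 were compared with Fisher's exact test. The ratio within an array blocks on the array; replicates 2 and 3 share a hybridisation day, and values within that day were fitted without the dye effect, which cancels in their mean.

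The fit was tested on simulated data made by shuffling each array's values among features of like intensity, with 200 of 14284 features changed, in 5 draws for the tethered against untethered comparison. It found 38.6% of features changed 2-fold and 97.4% of those changed 4-fold, with 15.4 false calls per draw. With replicate 4 scaled to the spread of the others, it found 96.2% and 100%, with 18.8 false calls per draw. Shuffling removed each feature's own spread and any dye bias shared between arrays. These rates therefore need not hold for the real features.

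The tests, the 24 gene lists and the rule for named genes were fixed before the data were examined. The rule named TMPO and up to 10 called genes per direction with the same sign on 4 arrays, or the 5 of smallest p where fewer than 3 were called. On chromosome 4 it named up to 5 called genes per direction, or the 3 of smallest p where fewer than 2 were called, and from each list with a called member or a test past 0.05 up to 4 members. Features without a name were passed over, and 1 gene that the rule picked is not reported here. ATP8A2 was measured on 3 arrays and lies outside the rule; it is named as the only call. Members of lists are named after their values were seen. Alternatives covered background, print-tip loess, median centring, scaling between arrays, filters on dim spots, the dye effect, array weights, thresholds, averaging of probes, the deposited value table and each array left out; all spots, a constant of 50 added to both channels, features usable on all 4 arrays and an unadjusted threshold were added after the data were seen. The choice between mean and median foreground could not be run, as each channel has 1 amplitude. The work used Python 3.11.15, pandas 2.3.3, matplotlib 3.10.9 and version 1.17.8 of data.table.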

Results

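Gene expression was compared between a pair of human cell lines that carry the same chromosome 4 insertion of bacterial lac operator repeats. In the tethered line, B49.5 74t3, a fusion of the lac repressor LacI with LAP2β, a protein of the inner nuclear membrane, was introduced to anchor the operator-bearing chromosome at the nuclear edge, whereas the untethered line, B49.5, had no such anchor. RNA from both lines was labelled with Cy3 and Cy5 and hybridised together to spotted two-colour arrays. There were 4 arrays, described by the labels as 4 biological replicates, with the tethered line in Cy5 on replicates 1 and 3 and in Cy3 on replicates 2 and 4. All ratios below are tethered over untethered on the log2 scale. The arrays differed in quality. Signal over background, as the scanner program reported it for Cy3 and Cy5, was 15.9 and 17.9 on replicate 1, 7.79 and 6.66 on replicate 2, 8.52 and 8.17 on replicate 3, and 4.14 and 2.41 on replicate 4. The SD of normalised log2 ratios was 0.775 on replicate 4, against 0.294, 0.275 and 0.275 on replicates 1, 2 and 3, and the small number of arrays limited the precision of every value.

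The first comparison asked which genes differ in expression between the tethered and untethered lines. Of 14284 features tested, 9590 of them named genes, 0 were called higher and 1 was called lower in tethered cells. The called gene was ATP8A2 on chromosome 13 (position 25492269, NCBI build 35), which encodes a phospholipid flippase, at −3.14 (SE 0.19, limma adjusted p = 0.0352, 3 arrays). Its value rested on replicate 4, where it was −6.07, against −0.05 on replicate 1 and −0.40 on replicate 3. Of its 2 spots, the one usable on replicates 1 and 3 was unusable on replicate 4, with a Cy5 amplitude of 333, and the value there came from the other spot, at 12566. In that spot the channel of tethered cells was not above background (Cy3 amplitude 217, probability of being on 0.02), so the sizes of −6.07 and −3.14 are ratios to an absent signal. With all spots used, ATP8A2 was at −0.43 (limma adjusted p = 0.953).

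Several genes that did not pass the test had like values on every array that measured them. CEP170, which encodes a centrosomal protein, was at 0.82 ± 0.17 (mean ± SD, n = 4 arrays), from 0.63 on replicate 1 to 1.00 on replicate 2. RAB27B on chromosome 18, a small GTPase of vesicle secretion, was at 0.84 ± 0.20 (mean ± SD, n = 4 arrays). Their limma adjusted p was 0.5 for both. BAMBI on chromosome 10, a decoy receptor of the TGF-β family, measured 1.45, 0.85 and 1.31 on replicates 1, 2 and 3, a mean of 1.20 ± 0.31 (SD, n = 3), with a limma adjusted p of 0.5. HSD11B1 on chromosome 1, the enzyme that regenerates cortisol from cortisone, measured −1.67, −1.47 and −1.02 on the same arrays, a mean of −1.39 ± 0.33 (SD, n = 3), with a limma adjusted p of 0.472. Replicate 4 gave no usable spot for BAMBI or HSD11B1, and with all spots used HSD11B1 was at −0.73 (limma adjusted p = 0.953).

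Most other genes with small p-values rested on 1 array. IFIT3, an interferon-induced gene on chromosome 10, had a fitted value of 1.58 (SE 0.18, limma adjusted p = 0.221), with 2.90 on replicate 2 against 0.30 and 0.20 on replicates 1 and 3. C1QB, a subunit of complement C1q, measured 2.56 on replicate 2, 0.51 on replicate 1 and −0.01 on replicate 3 (limma adjusted p = 0.441). Of the genes with negative values, HPS4, which acts in the formation of lysosome-related organelles, was at −5.58 on replicate 4 but −0.47 and 0.72 on replicates 1 and 3 (limma adjusted p = 0.147). ZBED3, a zinc finger gene, and SCN4A, a sodium channel of skeletal muscle, were at −3.29 and −2.57 on replicate 4 and between −0.03 and 0.12 on replicates 1 and 3, with limma adjusted p of 0.212 and 0.441. P2RX6, an ATP-gated channel, was the exception, with −0.46, −2.92 and −4.25 on replicates 1, 3 and 4 (limma adjusted p = 0.490). None of HPS4, ZBED3, SCN4A, P2RX6 and ATP8A2 had a usable spot on replicate 2.

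**Figure D1:**
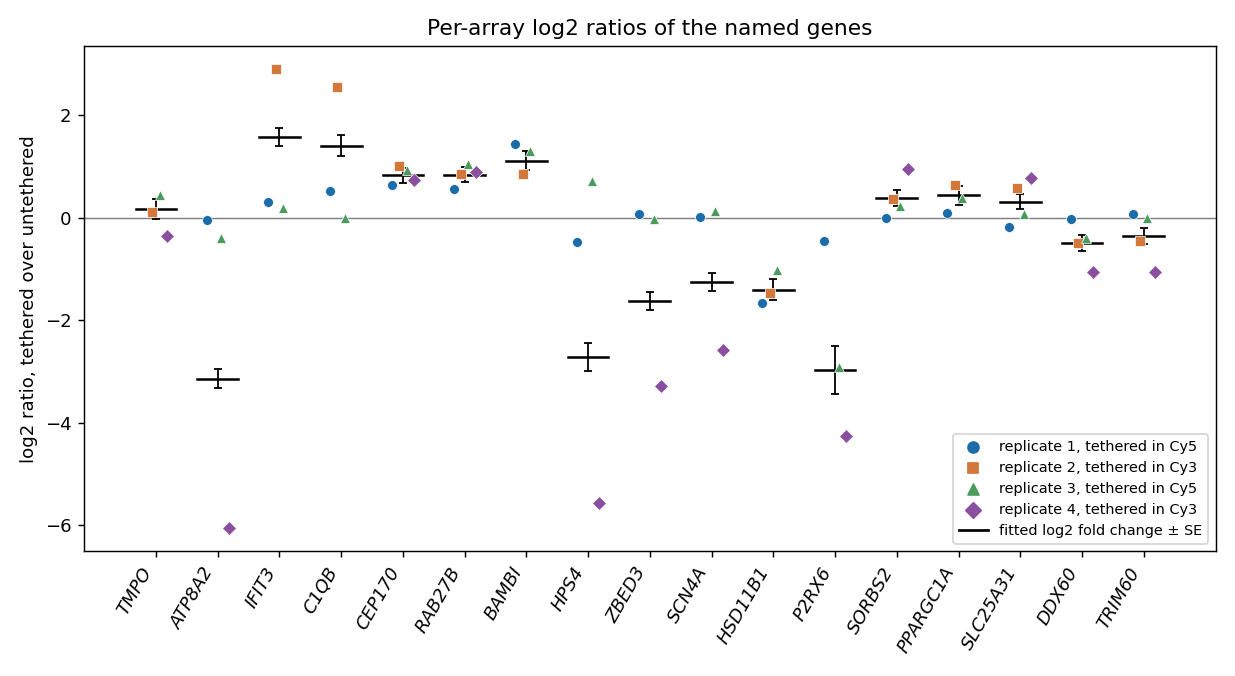
Log2 ratio of tethered over untethered cells (vertical axis) for each named gene (horizontal axis) on each array, with coloured points for replicates 1 to 4 and black bars for the fitted value ± SE. CEP170 and RAB27B had 4 points on 1 side of 0 and close together, whereas the bars of ATP8A2, HPS4, ZBED3 and SCN4A were set by replicate 4.

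Over all features, limma gave 545 with an unadjusted p under 0.05, of them 270 with positive and 275 with negative values, against 714 expected by chance. Of 10594 features measured on 4 arrays, 942 had the same sign on all 4, which is 8.89%, against 12.5% expected by chance. After the swapped arrays were turned, ratios across these features correlated at r = 0.200 between replicates 1 and 3 and at r = 0.058 between replicates 2 and 4, which share an orientation. Between orientations the turned ratios correlated at r = −0.055 (replicates 1 and 2), −0.264 (1 and 4), −0.069 (2 and 3) and −0.267 (3 and 4); genes are not independent replicates. The counts moved with the arrays used, to 2900 calls (1271 higher, 1629 lower) without replicate 2 and 119 (56 higher, 63 lower) without replicate 4. They also moved with scaling between arrays, which gave 10 higher and 13 lower, and within replicates 2 and 3, which share a hybridisation day and gave 7 higher and 5 lower.

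The TMPO gene encodes LAP2, the membrane part of the introduced fusion, and was examined for its own signal. TMPO on chromosome 12 (position 97427954, NCBI build 35) was at 0.16 (SE 0.20, limma adjusted p = 0.969), with 0.12, 0.45 and −0.36 on replicates 2, 3 and 4. Replicate 1 had only a spot of the lowest confidence class, at 0.81 when all spots were used, which brought the fitted value to 0.26 (SE 0.18, limma adjusted p = 0.953). With print-tip loess it was −0.04. The spread between arrays was larger than the value in each case. Whether the probe lies in exons of the β form, and the species of the introduced cDNA, are not given in the sources used here, so TMPO does not test the presence of the fusion or the direction of the ratios.

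The second comparison asked whether genes on chromosome 4, which bears the operator array, differ between the lines. No chromosome 4 gene was called among 515 features tested. Those with the smallest p and positive values were SORBS2, an adaptor of the actin cytoskeleton, at 0.38 (SE 0.16), PPARGC1A, a coactivator of mitochondrial biogenesis, at 0.44 (SE 0.19), and SLC25A31, a mitochondrial ADP/ATP carrier, at 0.31 (SE 0.14). Those with negative values included DDX60, an antiviral helicase, at −0.49 (SE 0.16), and TRIM60, a tripartite motif gene, at −0.36 (SE 0.16). The limma adjusted p was 0.969 for all of these. Without replicate 2, where replicate 4 is fitted exactly and 2900 features are called, SORBS2 (0.00466), DDX60 (0.000784) and TRIM60 (0.00593) passed. DDX60 measured −0.02, −0.50, −0.40 and −1.06 on replicates 1 to 4.

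As a set, chromosome 4 features had a median of −0.026, against −0.014 for all features tested. The set did not pass against all other features (camera adjusted p = 0.971, and 0.995 with an estimated correlation), which does not exclude a small difference. The median of chromosome 4 was below that of the other chromosomes on all 4 arrays, by a mean of −0.03 ± 0.01 (SD, n = 4); the exact two-sided sign-flip test gave p = 0.125, the smallest p that 4 arrays allow. Within replicates 2 and 3 the difference of fitted medians was −0.02. Among features with an unadjusted p under 0.05, 4 of 515 on chromosome 4 (0.777%) had positive values, against 1.95% elsewhere (two-sided Fisher's exact test, p = 0.0676), and 7 (1.36%) had negative values, against 1.92% elsewhere (two-sided Fisher's exact test, p = 0.508). None of 19 windows of 10 Mb along chromosome 4 passed, the smallest adjusted p being 0.461 at 100000001 to 110000000, where 27 features had a median of −0.11. The position of the operator array on chromosome 4 is not given in the sources used here. Of the other chromosomes, chromosome 10 had the smallest p, with a median of 0.04 over 533 features (camera adjusted p = 0.301).

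**Figure D2:**
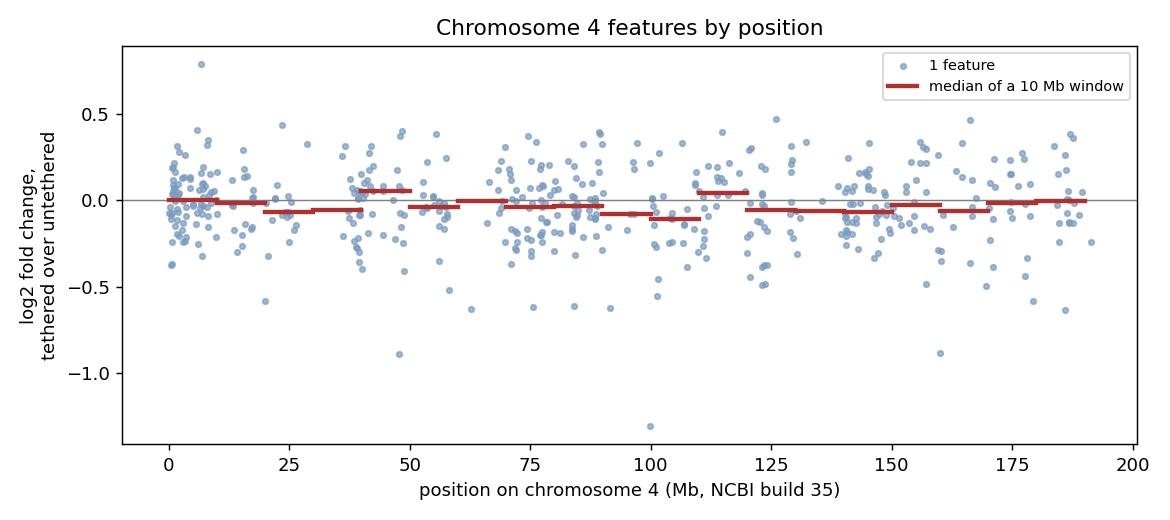
Fitted log2 fold change of tethered over untethered cells (vertical axis) for each feature on chromosome 4 by its position in NCBI build 35 (horizontal axis), with red lines for medians of windows of 10 Mb. The window medians lay between −0.11 and 0.05.

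The third comparison asked whether groups of related genes differ between the lines. No list of the 24 fixed in advance passed over all lists; limma's camera gave adjusted p from 0.354 to 0.900, and with an estimated correlation no list passed. IFIT3 was the only member of any list called when adjusted over the list alone (interferon response, limma adjusted p = 0.00217), on the single-array value given above. Of 20 measured interferon response genes 0 were called over all genes, and the list's median was 0.01.

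Genes of the nuclear envelope and lamina, among them TMPO, had a median of 0.00, with 8 of 16 measured members positive and 8 negative; none was called. Histone deacetylases and other repressors, enzymes and partners that act in gene silencing, had a median of −0.10, with 12 of 18 negative and 0 called. The chemokine cluster of chromosome 4 had a median of −0.10 over 7 measured genes, with CXCL1 at −0.30, CXCL3 at −0.33, CXCL5 at 0.23 and CXCL8 at 0.07, and 0 called. The median was 0.01 for inflammatory response genes and 0.05 for antigen presentation genes, again with 0 called.

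Genes of cell division differed in opposite ways between arrays. The list of G2 and M phase genes had medians of 0.57, −0.03, 0.23 and −1.59 on replicates 1 to 4, a mean of −0.20 ± 0.96 (SD, n = 4). CCNA2, the cyclin of S and G2 phases, followed them with 0.57, −0.44, 0.45 and −2.54, and BIRC5, which encodes survivin, with 0.75, −0.22, 0.12 and −2.07. Histone genes had medians of 0.18, −0.02, 0.29 and −1.99, and S phase genes 0.20, 0.06, 0.05 and −0.85. Fitted over all arrays, the list medians were −0.10 for G2 and M phase, −0.50 for histones and −0.14 for S phase, with 0 members called and camera adjusted p of 0.462, 0.354 and 0.462. The G2 and M phase list passed in opposite directions when single arrays were left out, with a median of 0.17 without replicate 4 (camera adjusted p = 0.0153) and −0.58 without replicate 2 (camera adjusted p = 1.36e-05). Histones and S phase genes moved likewise, to −1.05 and −0.35 without replicate 2 (camera adjusted p = 3.73e-07 and 0.00566) and to 0.10 and 0.08 without replicate 4 (0.302 and 0.276), and histones were at −0.51 without replicate 3 (0.00133). These values use camera's preset correlation of 0.01; over 4 arrays the estimated correlation was 0.623 within the G2 and M phase list, 0.195 within histones and 0.352 within S phase genes, and the adjusted p with it was 0.889 for each.

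Genes of the extracellular matrix, with a median of 0.08, had positive values for 14 of 19 measured members. Among them were COL5A1 (0.50, SE 0.18), LAMB1 (0.46, SE 0.16) and COL6A3 (0.36, SE 0.14), which encode collagen and laminin chains. Each was higher on replicates 2 and 4, with the tethered line in Cy3, than on replicates 1 and 3. On replicates 1 to 4 COL5A1 measured −0.04, 0.72, −0.21 and 1.55, LAMB1 0.23, 0.54, −0.07 and 1.15, and COL6A3 −0.06, 0.82, −0.14 and 0.80. MMP3, a matrix protease, had a fitted value of −0.67 (SE 0.18), set by −1.95 on replicate 4. It measured 0.48 and 0.73 on replicates 1 and 3 and had no usable spot on replicate 2. For the matrix list, the camera adjusted p was 0.354 (0.889 with an estimated correlation). It was 0.0104 when only features above background in both channels of all arrays were used. It was 0.0219, 0.0688 and 0.110 without replicates 1, 2 and 3, but without replicate 4 the median was −0.01 (camera adjusted p = 0.814). The medians of the matrix list were −0.06, 0.24, −0.07 and 0.48 on replicates 1 to 4. Glycolysis and hypoxia genes had medians of −0.10, 0.23, −0.46 and 0.47, with a fitted median of 0.04. Fitted medians were 0.06 for cytoskeleton genes, 0.12 for adhesion receptors and 0.03 for sterol synthesis genes. Of the sterol synthesis genes, SC5D was at 0.68 (SE 0.21) and NSDHL at 0.48 (SE 0.16). SC5D measured −0.11, 0.71, 0.17 and 1.95 on replicates 1 to 4. Of 19 measured sterol synthesis genes 9 were negative, among them FDFT1 at −0.42 (SE 0.20). No member of these lists was called.

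The lists of stress, housekeeping and early response genes had fitted medians of −0.02 for p53 targets, −0.09 for the unfolded protein response, 0.12 for heat shock, −0.07 for ribosomal proteins, −0.07 for oxidative phosphorylation and 0.01 for immediate early genes. Markers of other cell types had fitted medians of −0.04 (epithelial), 0.01 (haematopoietic), −0.01 (endothelial) and 0.01 (neural), each over 5 to 9 measured genes. None of these lists had a called member. For endothelial markers the median was negative and the mean positive, and for neural markers the reverse.

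**Figure D3:**
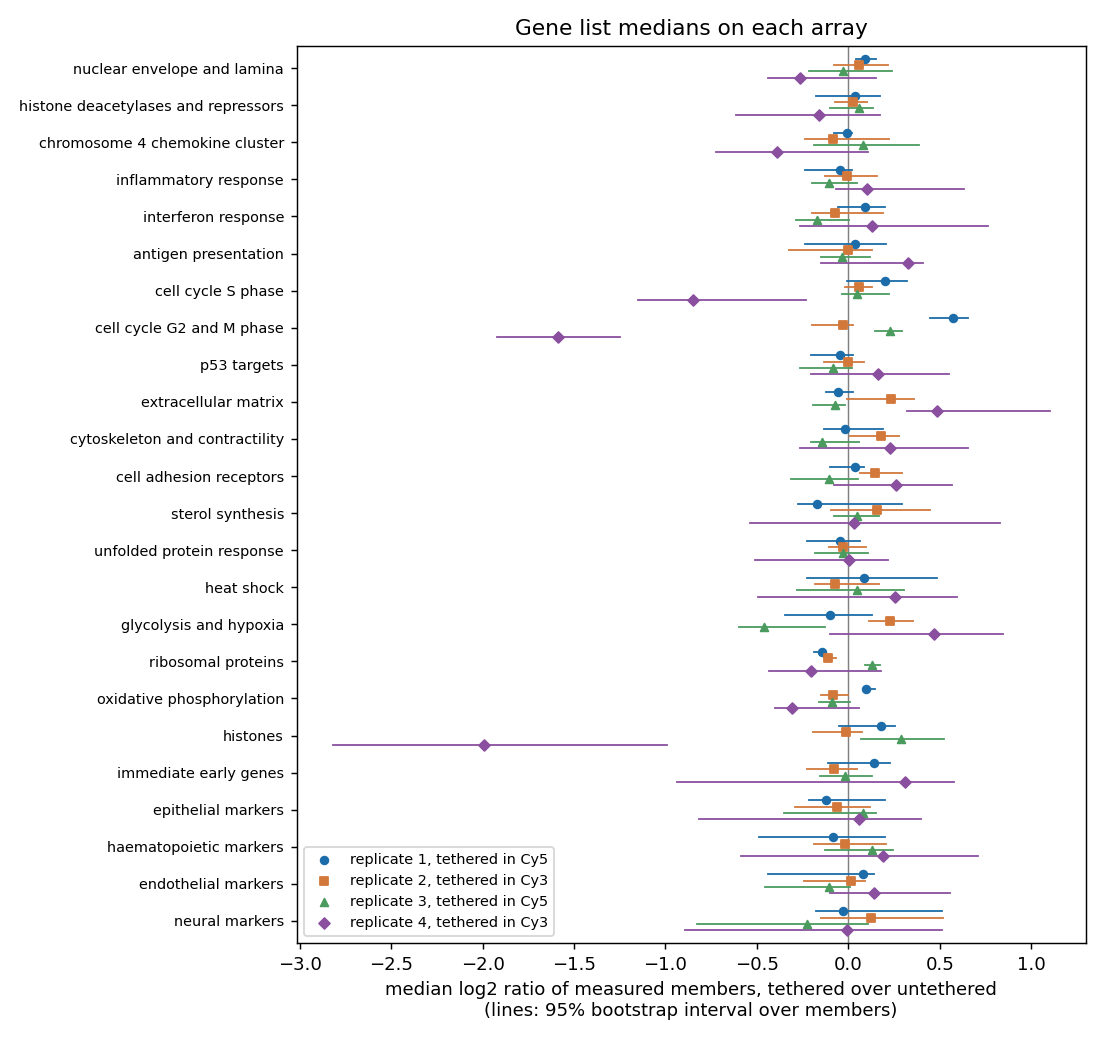
Median log2 ratio of tethered over untethered cells (horizontal axis) of each gene list (vertical axis) on each array, with 95% bootstrap intervals over the list's members. The medians of G2 and M phase genes lay at 0.57 and 0.23 on replicates 1 and 3 and at −1.59 on replicate 4.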

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

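Of 36 values tested for 1 array lying apart from the other 3, 4 passed, all on replicate 4. Chance flags about 5% of such groups if the arrays have equal spread. Replicate 4 had a wider spread, so chance would flag it more often. All explanations in this part were tested after the results had been seen. The SD of normalised log2 ratios was 0.775 on replicate 4, against 0.275 to 0.294 on the others. The median of histone deacetylases and repressors was −0.159 there (bootstrap interval −0.617 to 0.175), against 0.02 to 0.06. The S phase median was −0.851, against 0.05 to 0.20, and the histone median −1.99, against −0.02 to 0.29. Outside the measured genes, 1 of 98 blank or empty spots was on in both channels of all 4 arrays.

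Cell cycle genes of the G2 and M phase list ran with the Cy5 channel on replicates 1, 3 and 4 and, with the dyes as given, not with the line. A difference between the lines, with the dyes as given and no dye bias, would have put the medians of all arrays on the same side of 0. They were 0.57 and 0.23 on replicates 1 and 3, −1.59 (bootstrap interval −1.92 to −1.25) on replicate 4 and −0.03 (−0.20 to 0.03) on replicate 2. A line difference smaller than a dye bias would not be bound to 1 sign and stays open. A constant dye bias of each probe would have left replicate 2 level with replicates 1 and 3 in Cy5 over Cy3. Replicate 2 lay lower by a median of −0.343 (bootstrap interval −0.418 to −0.202). That interval is over members of the list and holds no spread between arrays. Replicates 1 and 3, of the same orientation, themselves lay apart at 0.57 and 0.23. The shift of replicate 2 therefore does not decide on a constant bias with spread between arrays. A bias that differs in size between arrays stays open, and so do dyes of replicate 4 recorded the other way round, which would put its median at 1.59 beside 0.57 and 0.23. A growth state that differed between the cultures of an array is a candidate explanation too: the SD of the list's median between arrays was 0.956, but culture and array are one in this design, so it cannot be told apart from the array.

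The number of calls between the lines rose from 1 to 2900 without replicate 2. In that fit replicate 4 is the only array of its orientation, so its own error is not in the residual, and calls that rest on it would share the sign of replicate 2 no more often than chance; of 2644 measured there, 50.8% had the same sign (exact 95% binomial interval 48.9% to 52.8%; genes are not independent). The sign on replicate 2 was taken from its ratio with the dye effect still in it. With the dyes as given, the share argues against line differences larger than the dye bias as the cause of these calls as a set. Smaller differences could take the other sign on replicate 2 and stay open. The unmeasured spread of replicate 4 would give such a share. The 119 calls without replicate 4 had the same sign on replicate 4 for 40.3% of 62 (interval 28.1% to 53.6%). Of the 3 splits of the arrays into pairs, 1, the labelled one, gave as many as 1 call and the others gave 0; 3 splits are too few to tell this from chance.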

How the results depend on the processing

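The count of genes changed, 1 (0 higher, 1 lower), was the same without a dim-spot filter, at an adjusted p of 0.10, with a 1.5-fold minimum, with the mean of probes and with 50 added to both channels. It was 0 with normexp at either offset, print-tip loess, both channels on in all arrays, no dye effect, all spots and features usable on all 4 arrays, with 102 to 742 features at an unadjusted p under 0.05 in limma. It was 3 (0 higher, 3 lower) with median centring, 4 (4 lower) with the deposited series values, 5 (1 higher, 4 lower) with array weights, 12 (7 higher, 5 lower) within the shared hybridisation day, and 23 (10 higher, 13 lower) with scale between arrays. Leaving out 1 array gave 0 to 2900 (0 to 1271 higher, 0 to 1629 lower), the highest without replicate 2, where replicate 4 is fitted exactly; the array weights can only weigh the orientations, 2.01 for replicates 1 and 3 and 0.496 for replicates 2 and 4. BAMBI, HSD11B1, IFIT3 and C1QB passed with scale between arrays and without replicate 4, HSD11B1 also within the shared day, and CEP170 and RAB27B without replicate 2 and without replicate 4. HPS4 passed with array weights, with the deposited values and without replicate 2, and ZBED3, SCN4A, P2RX6, SORBS2, DDX60 and TRIM60 passed without replicate 2. ATP8A2 did not pass with normexp, print-tip loess, no dye effect or all spots. TMPO did not pass in any setting that measured it, which leaves out those without replicate 2, 3 or 4 and the one usable on all 4 arrays, and moved by less than the SD between arrays, from −0.04 with print-tip loess to 0.28. The chromosome 4 median minus that of other chromosomes, −0.014, was negative in every setting and did not pass (adjusted p 0.402 to 0.997); it was −0.048 with both channels on in all arrays and −0.033 to −0.015 with 1 array left out. The share of chromosome 4 features called higher, 0%, was 0% to 8.10% with 1 array left out, where the 8.10% without replicate 2 lay below the 11.4% on other chromosomes (Fisher's exact test, p = 0.0425); the share called lower did not pass. No list passed in the main setting; with camera's preset correlation, 1 passed with both channels on in all arrays (extracellular matrix), with array weights (histones) and with features usable on all 4 arrays (extracellular matrix), and 1 to 3 with 1 array left out. The G2 and M phase median passed with opposite signs, −0.24 without replicate 1, −0.585 without replicate 2 and 0.17 without replicate 4. With an estimated correlation over 4 arrays, the adjusted p was 0.889 for extracellular matrix, histones and G2 and M phase. For the settings other than leaving out 1 array, the cause was not tested. The alternative foreground statistic was not run. Signal over background of 4.14 and 2.41 limits replicate 4, where 54.9% of spots were unusable, and with it the genes measured on 3 arrays.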

Other observations

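All tests in this part were chosen after the result had been seen. On replicates 1 to 3, without regard to replicate 4, 16 of 13242 features lay at least 0.75 from 0 on each array in the direction of the line, 11 of them higher and 5 lower in tethered cells. None was on chromosome 4. Those with names and positive values were BAMBI (mean 1.20 ± 0.31, SD, n = 3), ZNF117, a zinc finger gene (1.30 ± 0.27), CPED1 (0.93 ± 0.20), HMGN3, a nucleosome-binding protein (0.94 ± 0.11), NCALD, a neuronal calcium sensor (0.92 ± 0.18), and NPRL2, a regulator of mTORC1 signalling (0.92 ± 0.18). With negative values they were HSD11B1 (−1.39 ± 0.33) and PAEP, which encodes the lipocalin glycodelin (−1.17 ± 0.25). On replicate 4, CPED1 kept its sign at 0.12, whereas ZNF117 (−0.23), HMGN3 (−0.64), NPRL2 (−1.64) and PAEP (0.65) had the opposite sign. BAMBI, NCALD and HSD11B1 had no usable spot there. Of all features of this group measured on replicate 4, 7 of 9 had the opposite sign. The other 8 features had no gene name here; 1 of them, on chromosome 14, measured 1.49, 1.66, 1.83 and 0.97 on replicates 1 to 4 (limma adjusted p = 0.147) and passed with scale between arrays (0.00534), with array weights (0.0207) and within the shared hybridisation day (0.0146). Others of the 16 also passed in such settings, among them NCALD with scale between arrays and ZNF117 within the shared hybridisation day. Both settings hold arrays that were used to pick the features. None of the 16 passed in the main setting over 4 arrays.

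Features apart the same way on replicates 1 to 3 may mark a difference between the lines. Spread between arrays would give about as many features that turn with the swap as features that keep one sign of Cy5 over Cy3. The counts were 16 and 3 at a limit of 0.75, 31 and 25 at 0.5 and 5 and 2 at 1. Spread alone would also fill the arrangements where replicate 1 or replicate 3 has the opposite sign of Cy5 over Cy3. Those held 9 and 1 features at 0.5 and 0 at 0.75 and at 1, which argues against spread alone. A dye bias fills the one-sign arrangement too. Spread on top of a dye bias was left open, because an excess of more than 1.5 times was not met at 0.5. A constant dye bias of each probe keeps one sign of Cy5 over Cy3 on every array. Each of the 16 features had opposite signs on replicate 2 and on replicates 1 and 3, at least 0.75 from 0. They were picked for this, but a constant bias alone forbids it, which argues against that bias as their only source on replicates 1 to 3. Replicate 4 was not used to pick them. Of 9 measured there, 77.8% (exact 95% binomial interval 40.0% to 97.2%) kept the Cy5 over Cy3 sign of replicates 1 and 3. The other 22.2% (interval 2.81% to 60%) had the sign that a difference between the lines needs. With so few features, replicate 4 does not decide. Dyes of replicate 4 recorded the other way round stay open. All limits were chosen after the data were seen, and a difference between separately grown clones, unrelated to tethering, was not tested, as each condition is 1 line.

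Tested on the dye effect in place of the line, 6 lists passed with the preset correlation of camera: G2 and M phase genes (median 0.51, adjusted p = 2.53e-06), histones (0.81, 0.0028) and S phase genes (0.25, 0.0356) were higher in Cy5, and glycolysis and hypoxia genes (−0.38, 3.31e-05), extracellular matrix genes (−0.27, 0.0016) and adhesion receptors (−0.10, 0.0384) were lower. For histones, S phase genes and G2 and M phase genes the size came mostly from replicate 4. In Cy5 over Cy3, histones had medians of 0.18, 0.02, 0.29 and 1.99 on replicates 1 to 4. The S phase medians were 0.20, −0.06, 0.05 and 0.85, and those of G2 and M phase genes 0.57, 0.03, 0.23 and 1.59. Matrix genes (−0.06, −0.235, −0.07 and −0.48) and adhesion receptors (0.04, −0.15, −0.11 and −0.26) also lay farthest from 0 on replicate 4. No list passed the camera test of the dye effect with an estimated correlation, the smallest adjusted p being 0.744.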
